A study of Mus musculus with 6 samples.

How the data were processed

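RNA was measured by sequencing in mouse oocytes at the germinal vesicle stage, the fully grown oocyte before meiosis resumes. Per the labels, the 6 libraries formed 3 groups of 2: control oocytes, oocytes exposed to Sudan I (a synthetic azo dye), and oocytes exposed to Sudan I and given melatonin (a pineal hormone). The values used were raw read counts per gene symbol, deposited by the authors as 1 table with 24369 rows and 1 column per library. The labels state that libraries followed a standard Illumina protocol; the aligner, the counting program, the genome build, the dose, the route and the duration are not given in the sources used here. The labels do not say whether the 2 libraries of a group came from separate animals or pools, so every p-value measures only the spread between these samples.

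Total counts were 21993198 and 26065453 in control libraries 1 and 2, 24263428 and 21873655 in Sudan I libraries 1 and 2, and 20669373 and 24111362 in melatonin libraries 1 and 2. In 27 rows a date stood in place of a gene symbol; these held 0.256% of the counts, and the 23 that passed the count filter were tested but not named. Symbols were matched to the GENCODE M21 annotation of mouse genome build GRCm38 for positions and transcript lengths: 23457 matched directly, 789 as older synonyms and 123 did not match. This reference may differ from the build the authors used. Genes encoded by mitochondrial DNA were not analysed here.

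Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with its defaults on the group factor (minimum count 10), which left 14124 tested genes. Libraries were scaled by trimmed mean of M-values (TMM). All 6 libraries entered 1 edgeR quasi-likelihood fit with a mean per group and 3 residual degrees of freedom, with a common biological coefficient of variation of 0.167. Each of the 3 pairs of groups was compared by the quasi-likelihood F test. A gene was called changed at a Benjamini-Hochberg (BH) adjusted p under 0.05. Fold changes are on the log2 scale with the standard error (SE) of the fit. Levels (CPM) are counts scaled to the library's counts in tested genes multiplied by its TMM factor, with the standard deviation (SD) of 2 libraries. Where stated, levels are scaled to the library total instead. An exact permutation test of 2 libraries against 2 cannot give a two-sided p under 0.333, so none was used. The replicate numbers of the labels were not used as a block. The groups, tests, gene lists, named-gene rule and the alternatives not marked as added were chosen before the data were examined.

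Of 37 gene lists fixed beforehand, covering mitochondria, metabolism, stress and cell death, protein turnover, oocyte functions, chromatin, melatonin signalling and markers of other cells, 36 had at least 5 tested members. Each list was tested with camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, with BH adjustment over the lists within a comparison. Beside it stand camera with an estimated correlation, fry, and counts of members past 0.05 adjusted over all genes and adjusted over the list alone. The p printed for an estimated correlation is unadjusted unless stated otherwise. Fry tests whether a list's genes move on balance 1 way, and its mixed version whether they change in either direction; neither compares the list with other genes.

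Genes were named by a rule. The first part takes up to 8 genes per direction past the threshold with the largest fold change, filled to 4 per direction by the smallest unadjusted p where fewer passed. These needed a mean of at least 5 CPM and libraries of the 2 groups that did not overlap, and loci without a gene name were passed over. The second part takes up to 4 members with the smallest p in each list the text describes. The third part takes 20 genes of oxidative stress, apoptosis, dye metabolism, mitochondria and the oocyte, whatever their values. Of these, Cyp1a1 had 0 counts in all 6 libraries and mt-Co1 was not analysed here. Of the third part 1 more gene is not reported here, which left 17, and the text does not print every gene of the second part.

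Reversal of Sudan I differences in the melatonin group was measured on the 200 genes with the smallest p for Sudan I versus control, since fewer than 20 passed the threshold. The Sudan I libraries enter both fold changes, which favours opposite signs by chance. The observed values therefore stand beside 100 simulated data sets in which no group differed and 100 in which the melatonin group had the Sudan I mean for every gene. These were negative binomial counts with the fitted dispersions and real library sizes. Added after seeing the data, DESeq2 was run on the 14124 tested genes of the data and of the 100 sets in which no group differed, to count calls that comparisons share. Both tests were tried on 5 simulated data sets with 200 changed genes. EdgeR recovered 55.2% to 57.2% of genes changed by 1 on the log2 scale and 81.2% to 83.8% of those changed by 2. On average 10.8 to 16.6 of its 147.2 to 156.8 calls per comparison were false. For DESeq2 16.8 to 26.2 of 158.6 to 171.6 calls were false. In both tests the false share was above the level that the BH threshold aims at.

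The alternatives were median-ratio (RLE) and upper-quartile scaling, no count filter, a filter of at least 5 CPM in 2 libraries, DESeq2, limma-voom, the 2 groups fitted alone, the replicate number as a block, counts thinned to the smallest library total of 20669373, an absolute log2 fold change of at least 1, and each library left out in turn. Added after seeing the data were the edgeR likelihood-ratio test, a correction for transcript length (a spline per library with 4 degrees of freedom, with camera at both correlations), the number in each table column's code as a block, and a contrast of the 4 exposed libraries against the 2 control libraries.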

Results

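Transcript counts were compared in germinal vesicle oocytes from a control group, a Sudan I group and a Sudan I plus melatonin group, 2 libraries per group, with 20669373 to 26065453 counts per library. Between 16203 and 17006 genes were detected per library, and the 10 most abundant genes held 4.59% to 4.98% of the counts. The highest levels belonged to oocyte transcripts: Zbed3 averaged 8584 CPM ± 457 (SD, n = 6), Gdf9, an oocyte growth factor, 6177 ± 446, Nlrp14 5361 ± 368, Padi6 4683 ± 198, and Zp2, a zona pellucida protein, 3351 ± 308. The correlation of log2 CPM across genes was 0.978 to 0.984 for the 3 library pairs within groups and 0.978 to 0.987 for the 12 pairs between groups; genes are not independent replicates. Markers of cumulus and granulosa cells summed to 718 to 910 CPM per library, of which the 4 members with a mean of at least 50 CPM (Serpine2, Nr5a2, Esr2 and Gata4) held 72.0%.

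The comparison of Sudan I with control asks what exposure to the dye did to the oocyte's transcripts. Tex15, a germ-cell gene needed for meiotic recombination in males, rose 6.17-fold: 14.5 CPM ± 2.89 (SD, n = 2) in control oocytes and 89.6 ± 15.5 (SD, n = 2) in Sudan I oocytes. Its log2 fold change was 2.63 (SE 0.18, 95% interval 2.24 to 3.02, edgeR adjusted p = 0.00038). It was the only one of 14124 genes past the threshold in the edgeR quasi-likelihood test, and it passed under every alternative tried. In the 100 simulated data sets with no group difference, this test called 2.39 genes on average in this comparison (0 to 9). A count of 1 is therefore no more than such data give. Tex15 lies on chromosome 8 from 33516738 to 33585582 on the forward strand (GRCm38) and overlaps no other annotated gene. Rbpms, an RNA-binding protein gene 197 kb away and named here after its values were seen, stood at 65.3 CPM ± 5.32 in control and 94.3 ± 3.58 in Sudan I oocytes (n = 2 each), with a log2 fold change of 0.53 (SE 0.13, edgeR adjusted p = 0.9999).

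The next genes by p did not pass the threshold. Nipal2, of a family of magnesium transporters, had a log2 fold change of 2.77 (SE 0.36, edgeR adjusted p = 0.1004), from 1.78 CPM ± 0.195 to 12.1 ± 5.70. Mb21d2 had 1.73 (SE 0.27, adjusted p = 0.282) and Dhtkd1, a mitochondrial enzyme of lysine breakdown, 1.22 (SE 0.26, adjusted p = 0.9999). On the lower side stood Rassf4 at -2.04 (SE 0.33), Nfam1 at -1.34 (SE 0.27), Ica1l at -1.04 (SE 0.16) and Cd160 at -0.69 (SE 0.13), with edgeR adjusted p from 0.224 to 0.811. DESeq2 called 12 genes, 5 higher and 7 lower, and all 8 genes named by the rule were among them; limma-voom called 1. Without Sudan I library 1, edgeR called 4 genes, Mb21d2 and Nipal2 among them; it called 3 without control library 1, 2 without control library 2 and 2 without Sudan I library 2. At an unadjusted p under 0.05 there were 447 genes, fewer than the 706 chance would give, and the 95% interval lay within 1 log2 unit of 0 for 9878 genes (69.9%).

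**Figure D1:**
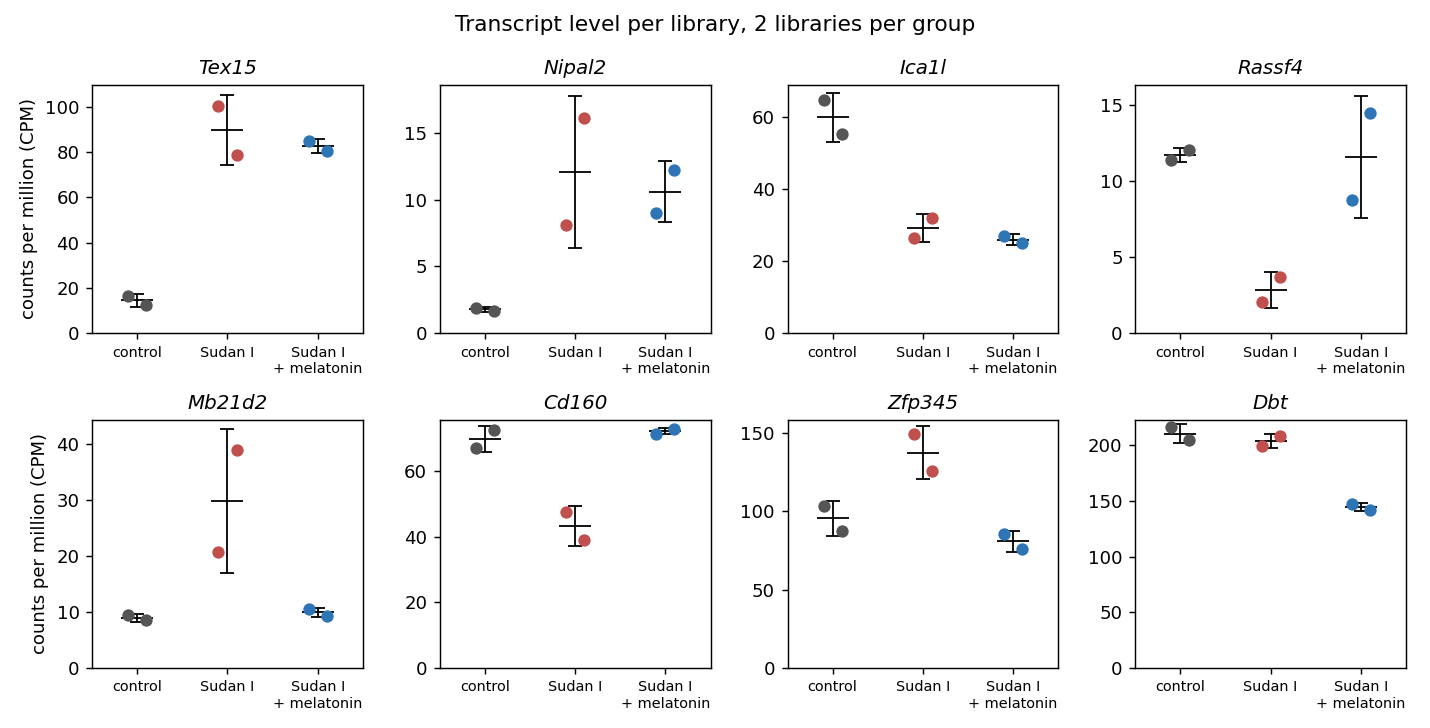
CPM of 8 genes in each library by group; points are libraries, and bars give the mean and SD of 2 libraries. Tex15 passed the edgeR threshold against control in both exposed groups, the other 7 genes in no comparison.

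None of the 17 genes picked in advance for oxidative stress, apoptosis, dye metabolism, mitochondria and oocyte identity reached an unadjusted p under 0.05. Among antioxidant enzymes, Sod1 had a log2 fold change of -0.07 (SE 0.11), Sod2 -0.19 (SE 0.16), Cat, the catalase gene, -0.62 (SE 0.42) and Gpx1 0.25 (SE 0.24). Among apoptosis genes, Trp53 had 0.01 (SE 0.15) and Bcl2 0.98 (SE 0.54), while Bax stood at 8.14 CPM ± 1.44 in control and 8.11 ± 0.190 in Sudan I oocytes (n = 2 each). The dye-sensing receptor gene Ahr had -0.05 (SE 0.16), its target Cyp1b1 0.04 (SE 0.27), Nqo1 -0.33 (SE 0.21) and Hmox1 0.30 (SE 0.47). The mitochondrial genes Dnm1l, Mfn2 and Tfam had -0.01 (SE 0.11), 0.03 (SE 0.15) and -0.20 (SE 0.14). Of the oocyte genes, Gdf9 stood at 5956 CPM ± 42.0 and 5972 ± 199 in control and Sudan I oocytes, Bmp15 had -0.09 (SE 0.17) and Zp3 -0.03 (SE 0.10). The 95% interval lay within 1 log2 unit of 0 for 14 of the 17, the exceptions being Cat, Bcl2 and Hmox1, all near 1 to 2 CPM.

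Immediate early genes, which respond within minutes to growth and stress signals, were lower in Sudan I oocytes: 18 of 19 tested members had negative fold changes, with a median of -0.42 (camera adjusted p = 0.0242; p = 0.385 with an estimated correlation). None passed the edgeR threshold, over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05: Egr1 at -0.57 (SE 0.15) and Jun at -1.58 (SE 0.69). Ier2 had -1.56 (SE 0.81) and Fosb -0.96 (SE 0.50). The granulosa list stood beside it with 19 of 30 members lower and a median of -0.18 (camera adjusted p = 0.435), Wt1 at -1.64 (SE 0.48) and Amh at -1.46 (SE 0.48), the product of Amh being a granulosa hormone. Library means of the immediate early list, relative to all 6, were 0.24 and 0.48 in control libraries 1 and 2 and 0.07 and -0.71 in Sudan I libraries 1 and 2; those of the granulosa list were 0.00 and 0.24, then 0.09 and -0.47.

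Theca, stroma and surface epithelium markers were higher in Sudan I oocytes, with 7 of 10 members positive and a median of 0.21 (camera adjusted p = 0.0432; p = 0.152 with an estimated correlation). Adjusted over the list alone, edgeR called 1 member, Cyp17a1, a steroid-synthesis enzyme of theca cells, at 0.141 CPM ± 0.0703 and 0.955 ± 0.0115 in control and Sudan I oocytes; over all genes it called 0, with 2 at an unadjusted p under 0.05 and 0 by DESeq2. Col3a1, a collagen of stroma, had 2.42 (SE 0.93). The theca call ended when any 1 of the 6 libraries was left out, and that of the immediate early genes ended without control library 1 (camera adjusted p = 0.315), control library 2 (0.252) or Sudan I library 2 (0.489), in a range of 3.75e-14 to 0.957 over all alternatives. With the replicate number as a block neither list passed. No list passed with an estimated correlation either (smallest camera adjusted p = 0.933).

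The remaining 34 lists did not pass in Sudan I versus control, with camera adjusted p from 0.435 to 0.906. In the stress lists, 21 of 32 antioxidant members were higher (adjusted p = 0.741, Prdx1 at 0.32, SE 0.14), as were 19 of 28 NRF2 targets and glutathione transferases, 8 of 16 aryl hydrocarbon receptor and xenobiotic genes, 9 of 31 unfolded protein response genes and 19 of 34 chaperones. In cell death, 12 of 27 pro-death genes were higher (adjusted p = 0.819, Pmaip1 at 1.85, SE 0.80), with 10 of 19 survival genes, 10 of 26 p53 targets, 37 of 63 DNA repair genes and 21 of 41 autophagy and lysosome genes. In mitochondria and metabolism the counts were 21 of 36 for respiratory complex I, 22 of 40 for complexes II to V, 45 of 77 for mitochondrial ribosomal proteins, 15 of 36 for mitochondrial dynamics, 13 of 19 for the TCA cycle, 13 of 23 for glycolysis and 12 of 28 for fatty acid oxidation. Protein turnover gave 21 of 32 proteasome subunits and 35 of 75 cytosolic ribosomal proteins (Rpsa at 0.88, SE 0.22).

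Among lists of oocyte function in the same comparison, 11 of 23 oocyte transcription and growth factors, 9 of 18 zona and fertilization genes, 13 of 31 maternal-effect genes and 30 of 43 meiotic resumption and cell cycle kinases were higher in Sudan I oocytes. Spindle and checkpoint genes had 29 of 46 higher (camera adjusted p = 0.741), meiotic cohesin and synapsis genes 14 of 26, actin cortex genes 16 of 38 and maternal mRNA storage genes 22 of 50. Chromatin modifiers had 21 of 55 higher, histone genes 9 of 19 and melatonin signalling genes 9 of 18. For other cells and stages the counts were 5 of 7 endothelial markers, 4 of 5 blood and immune markers and 3 of 11 genes of the zygotic activation list.

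**Figure D2:**
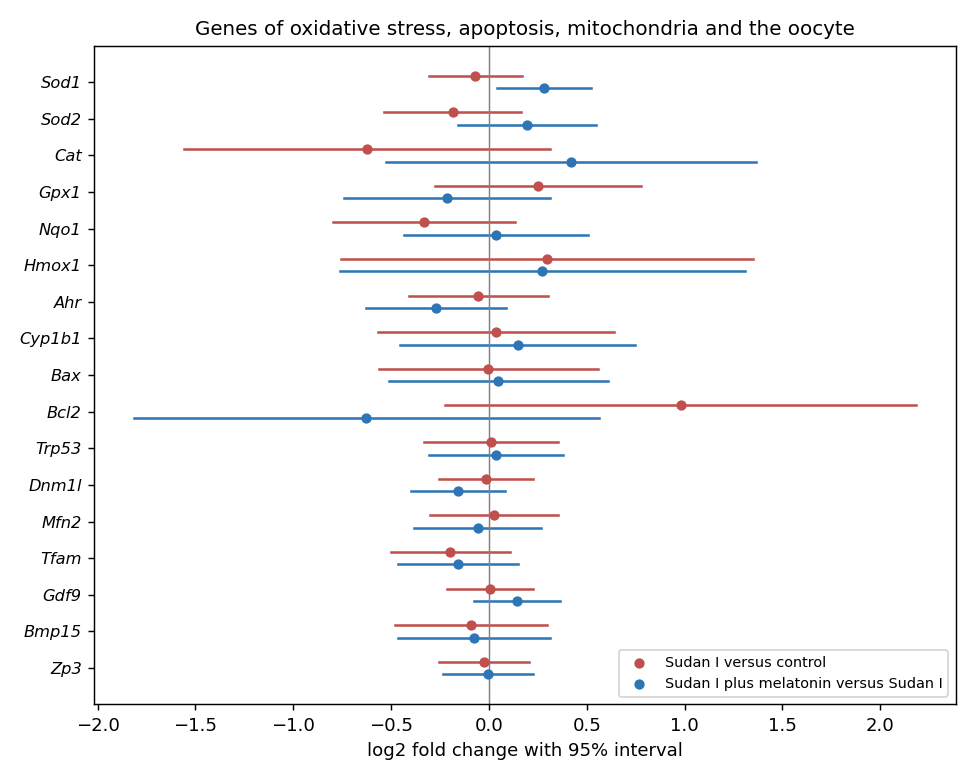
Log2 fold change with 95% interval of the 17 tested genes picked in advance, for Sudan I versus control and for melatonin versus Sudan I alone. None passed the edgeR threshold in either comparison.

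The comparison of Sudan I plus melatonin with Sudan I asks what melatonin did to exposed oocytes. Cytosolic ribosomal protein transcripts were higher with melatonin, 67 of 75 tested members being positive with a median log2 fold change of 0.22 (camera adjusted p = 6.57e-10; p = 0.117 with an estimated correlation). Respiratory complex I subunits were higher too, 28 of 36 with a median of 0.18 (camera adjusted p = 1.86e-05, and p = 0.191 with an estimated correlation). After adjustment no list passed with an estimated correlation (smallest camera adjusted p = 0.992). Examples are the ribosomal genes Fau at 0.71 (SE 0.20), Rpl38 at 0.97 (SE 0.33), Rpl32 at 0.67 (SE 0.25) and Rps15 at 0.38 (SE 0.15), and the complex I genes Ndufb11 at 0.36 (SE 0.12) and Ndufa6 at 0.43 (SE 0.15), none past the edgeR threshold.

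Complexes II to V (31 of 40 higher, median 0.14) and proteasome subunits (26 of 32, median 0.09) were also higher, with camera adjusted p of 0.0115 and 0.0201, and p of 0.385 and 0.457 with an estimated correlation. Mitochondrial ribosomal proteins followed with 53 of 77 higher and a median of 0.08 (camera adjusted p = 0.0201; p = 0.467 with an estimated correlation). Atp5k, an ATP synthase subunit, had 0.78 (SE 0.24), Mrpl54 0.70 (SE 0.21), Psmb3 0.44 (SE 0.19) and Psmb6 0.30 (SE 0.13). Adjusted over the list alone, edgeR called 0 members in each of the 5 lists, with 5, 3, 1, 3 and 2 at an unadjusted p under 0.05 in cytosolic ribosome, complex I, complexes II to V, mitochondrial ribosome and proteasome, and 0 by DESeq2. Library means of the ribosomal list were -0.16 and -0.02 in Sudan I libraries 1 and 2 and 0.05 and 0.28 in melatonin libraries 1 and 2, and the granulosa list stood at -0.40 and 0.53 in the melatonin libraries. Without melatonin library 2 no list passed (0 of 36), without Sudan I library 1 the ribosomal list alone did, without Sudan I library 2 the proteasome call ended, and without melatonin library 1 there were 7 calls. After a correction for transcript length, added after seeing the data, 2 of the 5 lists passed, the cytosolic ribosome and complex I, and with an estimated correlation 0 did.

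**Figure D3:**
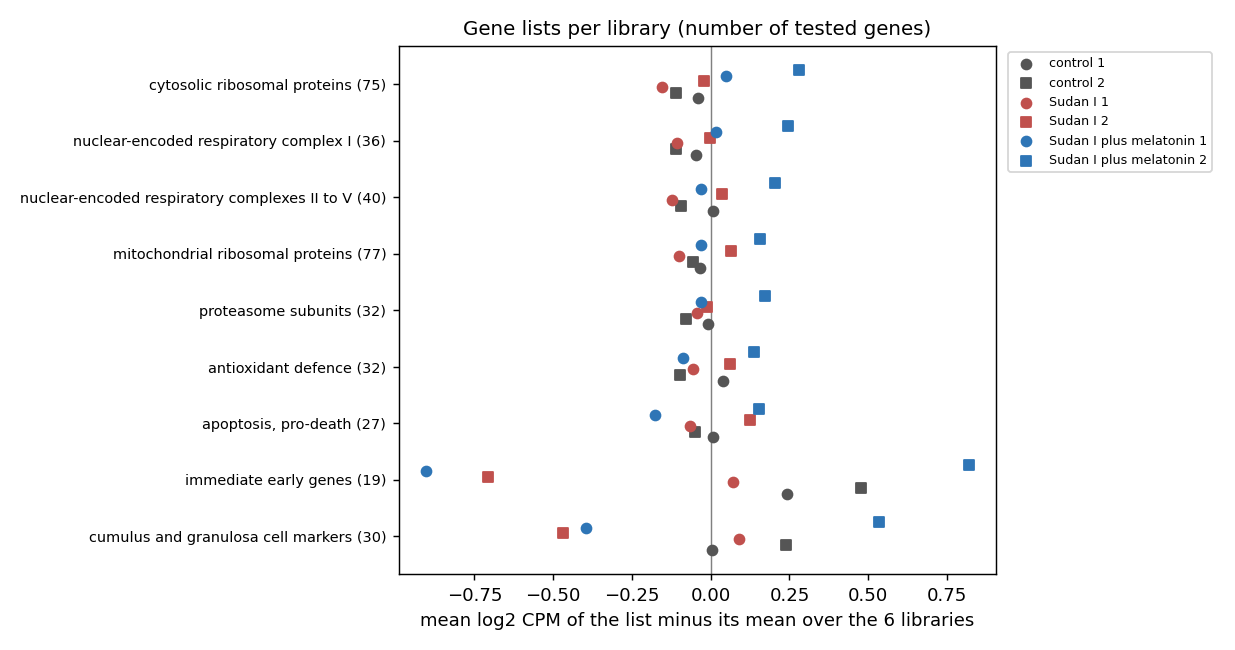
Mean log2 CPM of 9 gene lists in each library, relative to the mean of all 6 libraries; each point is a library, coloured by group and shaped by replicate number. Melatonin library 2 had the highest mean in each of the 9 lists.

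No single gene passed the edgeR threshold between the melatonin and Sudan I groups (0 of 14124, smallest edgeR adjusted p = 0.547), with 541 at an unadjusted p under 0.05, 6 called by DESeq2 and 0 by limma-voom. The genes with the smallest p were Rassf4, of the Ras-association family, at 2.03 (SE 0.34), Cd160 at 0.74 (SE 0.13), Pigyl at 0.63 (SE 0.14) and Chst9 at 1.76 (SE 0.41) on the higher side. On the lower side were Zfp345, a zinc-finger gene, at -0.77 (SE 0.13), Mb21d2 at -1.59 (SE 0.27), Dbt, of the branched-chain keto acid dehydrogenase, at -0.49 (SE 0.10) and Bbs2 at -1.32 (SE 0.27). Leaving out melatonin library 1 or melatonin library 2 gave 1 call each. The 95% interval lay within 1 log2 unit of 0 for 9902 genes (70.1%).

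Among the 17 genes picked in advance, Sod1, the cytosolic superoxide dismutase, had 182 CPM ± 4.09 in Sudan I and 221 ± 20.3 in melatonin oocytes (SD, n = 2 each), a log2 fold change of 0.28 (SE 0.11, edgeR adjusted p = 0.994), and was the 1 gene at an unadjusted p under 0.05. Sod2 had 0.19 (SE 0.16), Cat 0.42 (SE 0.43), Gpx1 -0.21 (SE 0.24), Bax 0.05 (SE 0.25) and Bcl2 -0.63 (SE 0.54). The antioxidant list had 17 of 32 members higher (camera adjusted p = 0.785), with Gss, a glutathione synthesis enzyme, at 0.73 (SE 0.24), Gpx4 at 0.51 (SE 0.25) and Prdx1 at -0.32 (SE 0.14). The pro-death list had 11 of 27 higher (camera adjusted p = 0.771), with Casp8 at -0.56 (SE 0.23). The immediate early list had 17 of 19 higher with a median of 0.46 (camera adjusted p = 0.297) and Egr1 at 0.29 (SE 0.15). The 31 lists that did not pass had camera adjusted p from 0.297 to 0.985.

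The comparison of Sudan I plus melatonin with control asks what still differed after melatonin. Tex15 rose again, to 82.8 CPM ± 3.18 (SD, n = 2), a log2 fold change of 2.51 (SE 0.18, 95% interval 2.12 to 2.90, edgeR adjusted p = 0.00057), and between the 2 exposed groups it differed by -0.11 (SE 0.16). The same 5 lists were higher as against Sudan I at the preset correlation. No list passed with an estimated correlation (smallest camera adjusted p = 0.997). Cytosolic ribosomal proteins had 61 of 75 members higher (median 0.24, camera adjusted p = 3.76e-07; p = 0.159 with an estimated correlation), and complex I had 32 of 36 (median 0.18, camera adjusted p = 6.27e-06; p = 0.178 with an estimated correlation). Complexes II to V had 31 of 40 (camera adjusted p = 0.00868; p = 0.394 with an estimated correlation), mitochondrial ribosomal proteins 58 of 77 (camera adjusted p = 0.000661; p = 0.350 with an estimated correlation), and proteasome subunits 27 of 32 (camera adjusted p = 0.00327; p = 0.385 with an estimated correlation).

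Examples among these lists were Rpl37 at 1.22 (SE 0.41), Rpsa at 0.75 (SE 0.22), Ndufa12 at 0.97 (SE 0.38), Ndufb2 at 0.80 (SE 0.31), Cox7c at 1.04 (SE 0.40), Uqcrh at 0.39 (SE 0.15), Mrpl52 at 0.88 (SE 0.29) and Psmd4 at 0.27 (SE 0.12). EdgeR called 0 members adjusted over the list alone in each of the 5, with 6, 4, 3, 2 and 1 at an unadjusted p under 0.05 in cytosolic ribosome, complex I, complexes II to V, mitochondrial ribosome and proteasome, and 0 by DESeq2. Without melatonin library 2 none of the 5 passed and 2 others did, immediate early genes and granulosa markers, both lower. Without control library 2 there were 2 calls, complex I and cytosolic ribosome, without melatonin library 1 there were 9, and after the transcript length correction 1, the cytosolic ribosome. The other 31 lists had camera adjusted p from 0.320 to 0.996. These include the antioxidant list with 18 of 32 members higher (adjusted p = 0.320, Gpx4 at 0.71, SE 0.25), the chaperone list with 15 of 34 (Cct6a at -0.87, SE 0.21; Hsp90aa1 at -0.25, SE 0.09) and the maternal mRNA storage list with 20 of 50 (Pabpc1 at -0.47, SE 0.14; Ddx6 at -0.55, SE 0.17).

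Tex15 was the only gene of 14124 past the edgeR threshold in this comparison, with 650 at an unadjusted p under 0.05, 12 called by DESeq2 (5 higher, 7 lower) and 1 by limma-voom. Simulated data with no group difference gave 2.2 edgeR calls on average here (0 to 10). Next by p were Nipal2 at 2.58 (SE 0.36), Chd2, a chromatin remodeller, at 1.58 (SE 0.37) and Rbpms at 0.65 (SE 0.13) on the higher side. On the lower side were Ica1l at -1.21 (SE 0.16), Gin1 at -1.82 (SE 0.30), Zfp715 at -1.09 (SE 0.19) and Dbt at -0.54 (SE 0.10). Their edgeR adjusted p ran from 0.0983 for Ica1l to 0.956 for Chd2. EdgeR called 3 genes without control library 1 and 2 genes each without control library 2, Sudan I library 1, Sudan I library 2 or melatonin library 1. Of the 17 genes picked in advance, Tfam, a factor for mitochondrial DNA, had -0.36 (SE 0.14) and was the 1 gene at an unadjusted p under 0.05; Ahr had -0.33 (SE 0.16), Sod1 0.21 (SE 0.11) and Hmox1 0.57 (SE 0.47). The 95% interval lay within 1 log2 unit of 0 for 9731 genes (68.9%).

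Whether melatonin turned back the Sudan I differences was measured on the 200 genes with the smallest p for Sudan I versus control. In 176 of them (88.0%) the change with melatonin had the opposite sign. Simulated data in which no group differed gave 91.8% (85.5% to 96.5%), since the same Sudan I libraries enter both changes, and data with Sudan I differences as fitted and no reversal gave 76.5% (63.6% to 86.4%). The latter take fitted differences, noise included, as true. They held 119.7 called genes and 1824 at an unadjusted p under 0.05, against 1 and 447 observed. They are therefore no fair reference for an absence of reversal. The sets with no group difference held 677 genes at an unadjusted p under 0.05 on average (614 to 769), also more than the 447 observed. Neither simulation therefore gives an exact reference for the 88.0%. The median of the melatonin-to-control change over the Sudan I-to-control change was 0.56, against 0.50 with no group difference and 0.81 with no reversal. Over all genes the Sudan I and melatonin changes had a covariance of -0.07, as in both simulations (-0.07 each), and a correlation of -0.45, weaker than in all 100 simulations with no group difference (-0.53 to -0.47). The covariance of the changes of the 2 exposed groups from control was 0.0877, above all 100 of those simulations (0.0651 to 0.0800). Genes were drawn independently in the simulations, while the real libraries differed in trends shared by many genes, such as that with transcript length. The simulated ranges may therefore be too narrow. Neither this correlation nor this covariance is shown to lie beyond chance. The share was 98.0% without Sudan I library 1 and 69.0% without control library 1. Rassf4, Cd160 and Mb21d2 had opposite changes in the 2 comparisons, and DESeq2 called the 3 in both, the edgeR quasi-likelihood test in neither; the edgeR likelihood-ratio test, added after seeing the data, also called the 3 in both. With the 14124 tested genes alone, DESeq2 called 12 and 9 genes and shared 5 of opposite sign, where simulated data with no group difference gave 5.02 and 4.67 calls and shared 0.77 of opposite sign on average (0 to 4). Any gene in which only the Sudan I libraries stand apart, from whatever cause, gives such a pair, so these calls do not show a reversal.

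Between the comparisons with control, the edgeR quasi-likelihood test shared 1 called gene, Tex15, where simulated data with no group difference shared 0.64 on average, and DESeq2 shared 3 (Tex15, Nipal2 and Ica1l), where such data shared 0.75 on average (0 to 5). At an unadjusted p under 0.05, 48 genes were higher in both and 74 lower in both, where independent comparisons would share 4.07 and 6.17. Both use the same control libraries, so sharing is expected without any difference: simulated data with no group difference shared 145 genes on average, whatever their direction, from lists of 677 and 675, against 123 observed from lists of 447 and 650. As the lists differ in size, the shared counts alone do not rank the data against the simulation.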

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

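The edgeR likelihood-ratio test, the transcript length correction and the column code block were chosen after the data were seen; the other alternatives were planned. Tex15 passed in both comparisons with control under every alternative run, and the counts of 1, 0 and 1 changed genes (Sudan I versus control, melatonin versus Sudan I, melatonin versus control) held with RLE and upper-quartile scaling, the 5 CPM filter, limma-voom, the 2 groups alone, the replicate block, thinned counts, the length correction and a log2 fold change of at least 1. Counts in the same order were 12, 6 and 12 with DESeq2 and 10, 11 and 11 with the likelihood-ratio test; the cause was not tested. With no count filter they were 88, 67 and 93, and with the column code as a block 139, 45 and 56. In both fits the estimated prior degrees of freedom of the spread became infinite, from 7.28 in the reported fit, so that every gene shared the fitted trend. Whether this raised the counts was not tested. The column code block also left fewer residual degrees of freedom than the 3 of the reported fit. The replicate block did not change these counts, but genes at an unadjusted p under 0.05 went from 447, 541 and 650 to 513, 635 and 771. Deviations of libraries with the same number correlated across genes by 0.05, 0.07 and -0.06. The labels do not say whether libraries of the same number were collected or prepared together. Whether the numbers pair the libraries is therefore not settled. Leaving out 1 library, with a lone library assumed to vary like the others, gave 1 to 4, 0 to 1 and 1 to 3 changed genes. The highest were 4 without Sudan I library 1, 1 without either melatonin library, and 3 without control library 1.

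The list calls numbered 2, 5 and 5. With an estimated correlation they were 0, 0 and 0, and with fry 0, 0 and 0, and the cause was not tested. For Sudan I versus control the replicate block gave 0 and the 5 CPM filter 1, the theca list then having too few members to test; the cause of the first was not tested. The length correction gave 2 calls for melatonin versus Sudan I and 1 for melatonin versus control. Leaving out 1 library gave 0 to 1, 0 to 7 and 2 to 9 calls; the lowest came without melatonin library 2 for both comparisons of the melatonin group (0 and 2, the 2 also without control library 2) and the highest without melatonin library 1 (7 and 9). The column code block gave 2, 6 and 5. The share of opposite signs (88.0%) was 86.0% with the replicate block, a cause that was not tested, and 69.0% to 98.0% with 1 library left out, the lowest without control library 1 and the highest without Sudan I library 1. DESeq2 shared 3 called genes between the comparisons with control, against 1 with the edgeR quasi-likelihood test. The range of genes detected was 803 across libraries and 677 after thinning.

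The 92 gene values of the text gave 1365 values over the alternatives chosen beforehand, other than the fold threshold. Of these 1287 kept their direction and side of the threshold, 54 came past it (32 with no count filter, 18 with DESeq2, 3 without Sudan I library 1 and 1 without Sudan I library 2), 0 fell short of it, and 24 changed sign, all in genes that did not pass. Of the added alternatives, the likelihood-ratio test brought 18 of the 92 past the threshold, the column code block 24 and the length correction 0, with 0, 5 and 3 changes of sign and 0 lost in each. In Sudan I versus control, Bax was 0.0035 with upper-quartile scaling and 0.018 with limma-voom, and Gdf9 -0.0024 with the 5 CPM filter; the cause was not tested. With 1 library left out, log2 fold changes there ran from -0.15 to 0.016 for Sod1, -0.16 to 0.57 for Gpx1, -0.17 to 0.19 for Bax, -0.15 to 0.18 for Trp53, -0.097 to 0.18 for Cyp1b1, -0.17 to 0.058 for Ahr, -0.028 to 0.037 for Gdf9, -0.38 to 0.15 for Bmp15, -0.12 to 0.072 for Zp3 and -0.13 to 0.097 for Dnm1l. For melatonin versus Sudan I they ran from -0.53 to 0.20 for Gpx1, -0.23 to 0.28 for Bax, -1.17 to 0.25 for Bcl2 and -0.28 to 0.074 for Tex15. Leaving out the genes of mitochondrial DNA was not run, as no such gene was tested. With 2 libraries per group at this depth, the 95% interval excluded a change of 1 log2 unit either way for 68.9% to 70.1% of genes.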

Other observations

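Every test in this part was chosen after the result it concerns was seen, except the test of chromosome segments, which was written down before its result. The 4 libraries exposed to Sudan I, with or without melatonin, were set against the 2 control libraries. Tex15 (log2 fold change 2.57, SE 0.16) and Nipal2 (2.67, SE 0.34) rose and Ica1l fell by 1.12 (SE 0.13), with edgeR adjusted p of 0.000233, 0.0480 and 0.0335. These 3 were the genes past the threshold, and 558 had an unadjusted p under 0.05. All 4 exposed libraries lay above both controls for Tex15 and Nipal2 and below both for Ica1l, a gene related to an islet cell autoantigen. Over 11 alternatives Tex15 passed in 11 (adjusted p 4.82e-05 to 0.00449), Ica1l in 6 (0.0254 to 0.243) and Nipal2 in 4 (0.00515 to 0.965). The next genes by p with a mean of at least 5 CPM, not past the threshold, were Gin1 at -1.47 (SE 0.24), Scamp5, a secretory carrier membrane protein gene, at -0.64 (SE 0.12) and Rbpms at 0.59 (SE 0.12). Col9a2, at -2.88 (SE 0.56) with a mean of 1.65 CPM, stood between Scamp5 and Rbpms by p.

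Transcripts of the cytosolic ribosome, respiratory chain, mitochondrial ribosome and proteasome were higher in the melatonin group, and they are short, with median lengths of 1049 to 1851 bases against 3340 for all tested genes. The rank correlation across genes of a library's deviation with transcript length was -0.46 in melatonin library 2 and -0.18 in Sudan I library 2, and 0.15 to 0.26 in the other 4. With the length trend removed, 1 of the 8 calls of the 4 lists other than cytosolic ribosome was kept (complex I against Sudan I, mean 0.20 before and 0.12 after, SD 0.23), so the trend is a candidate explanation for those lists; the cytosolic ribosome mean against Sudan I went from 0.26 (SD 0.33) to 0.18 (SD 0.32) and that against control from 0.26 (SD 0.33) to 0.14 (SD 0.33), and the list stayed past the threshold in both comparisons at the preset correlation (camera adjusted p = 9.95e-05 and 0.0468, with ranges over all alternatives of 9.69e-12 to 0.992 and 3.83e-10 to 0.997 for the cytosolic ribosomal proteins). With an estimated correlation it did not pass before the correction (p = 0.117 and 0.159, adjusted 0.992 and 0.997) or after it (p = 0.0505 and 0.118, adjusted 0.910 and 0.941), so the trend as its whole cause stays open. The share of counts in Rn45s, a ribosomal RNA precursor, was 0.0424% in melatonin library 2, 0.0396% in Sudan I library 2 and 0.0193% to 0.0311% in the other 4. It followed the length correlation (Pearson r = -0.93, exact permutation p = 0.00139, adjusted 0.00278; Spearman rho = -1, p = 0.00278, adjusted 0.00556; 2 relations), and with the cytosolic ribosome means it gave r = 0.76 (p = 0.0542, adjusted 0.0542; Spearman rho = 0.77, p = 0.103), so a difference in RNA or library quality stays open for that list. Granulosa RNA stays open for the cytosolic ribosome list, whose library means correlated with the granulosa list's by r = 0.34 (exact permutation p = 0.538; Spearman rho = -0.03, p = 1; r = -0.88 without Sudan I library 2 and melatonin library 2; 2 relations, adjusted p = 0.538). Melatonin itself cannot be told apart from differences between single libraries. Both melatonin libraries lay above the other 4 in 2 of the 5 lists. In cytosolic ribosome, melatonin libraries 1 and 2 stood at 0.05 and 0.28, against at most -0.02 in the other 4. After the length correction these means were 0.07 and 0.14, against at most -0.015. In complex I they stood at 0.02 and 0.25, against at most -0.002. In the rest of the 5 lists only melatonin library 2 lay above the other groups.

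Immediate early genes were lower in Sudan I oocytes, and their library means followed those of the granulosa markers over the 6 libraries, with Pearson r = 0.97 (exact permutation p = 0.00556, adjusted 0.0111) and Spearman rho = 0.89 (p = 0.0333, adjusted 0.0667), over 720 permutations and 2 relations. The value was r = 0.97 without Sudan I library 2 and melatonin library 2, and the lists share 0 genes. That value rests largely on melatonin library 1, at -0.40 in the granulosa list and -0.90 in the immediate early list. The other libraries kept lay at 0.00 to 0.24 and 0.07 to 0.48. Inha ran from 21.3 to 94.4 CPM and Gja1 from 12.9 to 60.8, highest in melatonin library 2 and lowest in Sudan I library 2, and Jun from 3.87 to 33.7, so a varying amount of RNA from attached granulosa cells may explain part of the immediate early signal. These genes and the next were picked after their values were seen. Their levels in this paragraph are scaled to the library total, without the TMM factor. Not every gene followed this order: in libraries 1 and 2 of the group, Egr1 stood at 90.8 and 101 CPM in control and 64.1 and 65.2 in Sudan I oocytes, and the granulosa gene Amh at 19.2 and 21.3, then 7.75 and 6.95. Inhbb stood at 15.1 and 4.41, then 35.8 and 4.39, and Dusp1 at 77.1 and 52.5, then 55.7 and 71.6. An effect of Sudan I cannot be told apart from it: the lowest control library lay above the highest Sudan I library by 0.17, and libraries within a group lay up to 1.72 apart. No label states whether or how the cells around the oocytes were removed.

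Tex15 was higher in all 4 exposed libraries. Among the 4 tested genes within 100 kb, the highest upper 95% limit was 1.10 (Gsr), below the lower limit of 2.20 for Tex15. This argues against transcription spreading from any of these genes having risen about as much. Spreading from a neighbour whose own level did not change, or from a gene below the count filter, was not tested. Rbpms, 197 kb away, stood at 0.59. Tex15 rose by 71.4 CPM, while marker lists of granulosa, theca and stroma, endothelial and blood cells differed in summed CPM by at most 15.6 (granulosa) between exposed and control libraries. These sums cannot decide on RNA of other cells, as granulosa sums ran from 718 to 910 CPM and the Tex15 level of such cells is not known here. Cyp17a1 and Col3a1, with log2 fold changes near that of Tex15, rose by only 0.686 and 0.387 CPM. These rises and the differences of 71.4 and 15.6 are scaled to the library total, without the TMM factor. Sudan I library 2, with Tex15 at 78.7 CPM, had the lowest granulosa mean of the 6 (-0.47). Melatonin library 1, with Tex15 at 85.0 CPM, had the lowest theca mean of the 6 (-0.28). This order argues against granulosa or theca RNA as the whole source. RNA of other germ cells was not tested. A genetic difference between the sources of the oocytes stays open. The 100 genes with the smallest p held 5 pairs within 1 Mb, against a median of 8 in 10000 random sets. Under the rule written beforehand, a count at or below the median spoke against wide chromosome segments. That verdict is set aside here, on a condition that the written rule did not hold. With 558 genes at an unadjusted p under 0.05, where chance gives 706, most of the 100 can be noise. A segment around a single locus would also add few pairs. An effect of Sudan I was not tested apart from a genetic difference.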
